A study of Mus musculus with 2 samples.

How the data were processed

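Chromatin immunoprecipitation followed by sequencing (ChIP-seq) for monomethylated lysine 4 of histone H3 (H3K4me1), a histone mark found at enhancers and beside promoters, was performed on mouse embryonic facial prominence, the tissue that builds the upper and lower face. Per the labels, the embryos were 14.5 days old, of a B6 strain background and of both sexes, pooled. Biological replicate 1 came from 24 embryos and biological replicate 2 from 34 embryos, and both libraries had a size range of 300 to 500 bp. The 2 samples form 1 group, so no contrast between conditions, ages or tissues could be made.

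The authors deposited peak lists in narrowPeak format on the mm10 assembly, per the file headers: 1 list for each replicate, 1 list called on both replicates together (the pooled list) and 1 list of replicated peaks, derived from the pooled list and both replicate lists. The signal of each peak is the deposited value of the authors' peak caller, and what it is relative to is not given in the sources used here. The significance of each peak is deposited as −log10 of its p-value and of its q-value. The lowest −log10 p was 2.03 in the replicated list and 2.02 in the list of replicate 2. The aligner, the peak caller, its threshold and the rule that made the replicated list are not given in the sources used here. The file lists name 2 inputs besides the alignment for the peaks of replicate 1 and 1 for those of replicate 2, without stating what they are. The deposited peak lists hold no read counts, so the depth of each library is unknown, and no interval that needs depth is given. A peak's signal and significance served to describe, rank and filter peaks within a list. Between lists, signal was correlated and given side by side for named peaks, the share of peaks past a q-value limit was compared, and signal was scaled down in a test of the X chromosome. Values of different lists are not on a known common scale. Peaks and genes are not replicates: the replicate number is 2 throughout, and tests over genes or peaks describe these libraries.

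Peaks were set against the mouse reference of the same build with GENCODE M21 annotation; of the 82470 replicated peaks, 0 lay beyond a chromosome end. Replicates were compared by the share of peaks with at least 50% of their length covered by peaks of the other replicate, by the Jaccard index of covered base pairs, and by the rank correlation of signal at replicated peaks. Chance overlap came from 100 circular shifts of all peaks along their chromosomes. Peak midpoints were placed, in this order, in promoters (within 1 kb of a transcription start site, TSS), exons, introns or intergenic sequence, and peaks over 2 kb from every TSS were called distal. The share of protein-coding TSSs covered was taken every 100 bp out to 5 kb on each side. TSSs with an observed-to-expected CpG ratio of at least 0.6 within 500 bp were called CpG-rich.

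For each protein-coding gene, the covered length within 50 kb on either side of the TSS was summed. The medians of 17 gene lists, 372 genes in all, were compared with 10000 random lists, in which each gene was replaced by a gene drawn at random from the same of 10 bins by the number of neighbouring TSSs, so that a gene could be drawn more than once. The two-sided p from the rank of the observed median was adjusted over the 17 lists by the Benjamini-Hochberg method at 0.05. 8 genes stood in more than 1 list, and a window also takes in peaks of neighbouring genes. Matches of 21 sequence motifs per kb were compared between peaks and flanks of the same width 5 kb away that held no pooled peak, with 95% intervals from 1000 bootstraps over chromosomes, and no ratio was given below 10 matches. The intervals cover variation between chromosomes, not between animals. In 1 alternative, peaks were paired with flanks within 2 percentage points of GC content, which kept 25442 of the 82470 peaks in 28580 pairs.

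The comparisons, gene lists, motifs and rule for named genes were fixed before the data were examined. The rule took the 2 most and the 1 least covered gene of each list, the 10 most covered protein-coding genes at least 200 kb apart, the 10 nearest genes of the replicated peaks with the highest signal (1 peak per gene), and the 5 genes in each direction with the largest difference between replicates. Alternatives changed the peak list, the single replicate used, the q-value limit (0.01), the share of peaks kept (the 50% with the lowest p-values, called the strongest peaks), the overlap needed, the promoter width, the gene window (20 or 100 kb), the matching of random lists and the sequence searched. Added after seeing the data were the removal of X-linked genes, matching on window GC, runs of neighbouring genes for the Hox clusters, unmasked sequence with and without GC matching, and peaks per unmasked Mb.

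The procedures were tested on simulated data. With 40.1% of 136672 peaks left in place and the rest shifted, the overlap came out at 40.8%. Of 200 random lists (n = 20 genes each, among 21728), 4% passed p = 0.05 unadjusted with coverage unchanged, 52.5% with coverage raised 2-fold and 92% with coverage raised 4-fold, so that 2-fold differences of short lists were often missed. Planted motif ratios of 1 and 1.5 over 9024 peaks came out at 0.962 and 1.52. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.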

Results

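H3K4me1 was mapped in facial prominence of mouse embryos at 14.5 days of development, in 2 biological replicates. The replicate 1 list held 136672 peaks over 51.7 Mb and the replicate 2 list 111621 peaks over 38.8 Mb. The pooled list held 161015 peaks over 74.4 Mb, and the replicated list 82470 peaks over 53.1 Mb, or 1.95% of the genome. Replicated peaks had a median width of 510 bp and a median deposited signal of 3.39. Of the peaks in replicate 1, 69.3% had a q-value of 0.01 or less, against 43.3% in replicate 2. Read depth is unknown.

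The first comparison asked how far the replicates marked the same places. Of the peaks in replicate 1, 33.4% had at least 50% of their length covered in replicate 2, and 47.8% of the peaks in replicate 2 were so covered in replicate 1. The Jaccard index was 0.283. Circular shifts gave at most 1.70% and 2.37% for the shares and 0.0106 for the index, so sharing was far above chance. The shares depended on the overlap required: with 80% of the peak length they were 16.7% and 30.1%.

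Covered length within 50 kb of the TSS had a Spearman correlation of 0.947 between replicates across 21728 protein-coding genes, which are not independent. Deposited signal, another quantity, had a Spearman correlation of 0.301 and a Pearson correlation of 0.350 across the 55718 replicated peaks touched in both replicates. Replicate 1 covered more than replicate 2 around Cxxc5, a zinc finger regulator of Wnt signalling, with 23.4% against 12.6% of the window. Smad3, a transducer of TGF-beta signals, had 27.4% against 17.9%, and Ptn, which encodes the growth factor pleiotrophin, had 17.6% against 8.52%. Cpa1 (27% against 17.8%) and G430095P16Rik (36.1% against 26.5%) were the other genes with the largest differences. Replicate 2 covered more around Rspo1, a Wnt agonist, with 9.79% against 5.69%. It also covered more around Trps1, a zinc finger repressor of transcription that acts in cartilage and hair follicle development, with 6.27% against 2.73%. Ptk7, a planar polarity receptor, had 21.8% against 18.4%, Foxo6 9.15% against 5.78%, and the T-box gene Tbx3 7.38% against 4.22%. With 1 value per replicate these differences have no test, and replicate 1 covered more of the genome.

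Every replicated peak was identical to a pooled peak, and 51.2% of pooled peaks were kept. The kept peaks were wider and stronger, with a median width of 510 bp and signal of 3.39, than the 78545 peaks left out, with 243 bp and 2.68. At 50% of the peak length, 76.1% of replicated peaks were covered in replicate 1, 59.6% in replicate 2 and 43.7% in both. The share in both was 67.6% when 1 bp was enough and 66.7% when 50% of either peak was enough. Under the last rule 27477 replicated peaks were still not found in both lists, while 0 of the peaks left out met it in both.

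The next comparison asked where in the genome the mark lay. Of the replicated peaks 69.6% were distal, fewer than in any circular shift (mean 88.4%, lowest 87.7%), 49.8% lay in introns and 26.4% between genes. Promoters held 19.9% of peaks, 3.13 times the mean of the circular shifts (6.35%, range 5.94% to 6.81%). Introns were also above their shifts (40.3%, highest 41.7%), exons held 3.90% (highest shift 3.71%), and intergenic sequence held fewer peaks than any shift (lowest 48.0%). The single replicates had 17.6% ± 0.286 of peaks in promoters and 72.5% ± 0.507 distal (SD, n = 2). With promoters drawn at 2 kb their share was 30.4%.

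Among the replicated peaks with the highest deposited signal, taken once for each of 10 nearest genes, 7 lay in introns. The strongest replicated peak, with signal 8.97, lay in an intron of Tead3 (mm10 chromosome 17, 28343755 to 28346652), which encodes a DNA-binding partner of the Hippo pathway. Strong intronic peaks also lay in Bahcc1 (chromosome 11, 120258635 to 120262922, signal 8.69), in Cic, a repressor acting downstream of receptor tyrosine kinases (chromosome 7, 25280057 to 25281833, signal 8.46), and in Tpcn1, an endolysosomal channel gene (chromosome 5, 120564582 to 120569337, signal 8.32). Introns of Kirrel (8.19), the inhibitory Smad gene Smad6 (8.18) and the corepressor gene Ncor2 (7.97) held 1 such peak each. An intergenic peak of 5490 bp lay 13.2 kb upstream of Ski, which encodes a repressor of TGF-beta signalling (chromosome 4, 155233002 to 155238491, signal 8.32). Peaks nearest to Sertad4 and C1qtnf5, both with signal 8.04, were centred 21.5 kb and 1.88 kb downstream of the TSS of these genes and within 1 kb of another annotated TSS. The peak near Sertad4 had signal 4.63 in replicate 1 and 9.36 in replicate 2, and the Tead3 peak 8.30 and 5.4.

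Around the TSS the mark formed 2 shoulders with a dip between them. Replicated peaks covered 5.66% of the 21728 protein-coding TSSs themselves, 12.1% of positions 600 bp upstream and 22.0% of positions 1100 bp downstream. The downstream shoulder was 3.90 times the value at the TSS, and 3.71 ± 0.145 times in the single replicates (SD, n = 2). Among 10060 genes with CpG-rich promoters, 3.47% of TSSs were covered, 19.6% of positions 800 bp upstream and 38.2% of positions 1100 bp downstream. Among 11668 CpG-poor genes the dip was shallower, with 7.54% at the TSS, 8.41% at 300 bp upstream and 9.18% at 800 bp downstream. The split by CpG content was described and not tested.

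**Figure D1:**
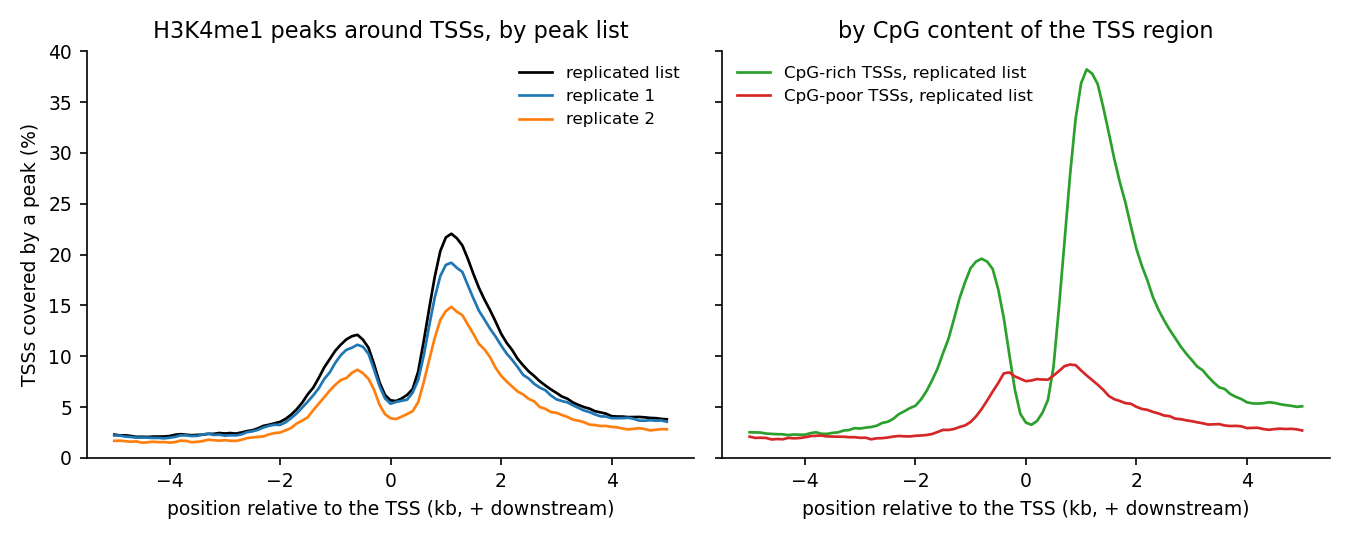
Percentage of protein-coding TSSs covered by an H3K4me1 peak (vertical axis) against position relative to the TSS in kb (horizontal axis), for the replicated list and each replicate (left) and for CpG-rich and CpG-poor TSSs (right). All 3 lists in the left panel dip at the TSS and are highest 1100 bp downstream, and the CpG-rich curve reaches 38.2% there.

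Gene lists were then used to ask around which genes of the developing face, and of other tissues, the mark was broad. 2 lists had more coverage than random lists. The 39 genes of palate and facial signalling had a median of 5.77 kb covered within 50 kb of the TSS, against 1.32 kb in random lists (central 95% 0.553 to 2.42 kb, n = 39 genes, adjusted p = 0.0017). The 40 transcription factors of cranial neural crest and facial mesenchyme had 4.40 kb, against 1.38 kb (0.588 to 2.42 kb, n = 40 genes, adjusted p = 0.0017). Their unadjusted p, 0.0002 in both (n = 39 and n = 40 genes), is the smallest that 10000 random lists can give. Over replicates the medians were 5.05 ± 1.3 kb and 3.93 ± 1.12 kb (SD, n = 2), and both lists passed under each alternative peak list, window, measure and matching that was run.

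In the facial transcription factor list 38 of 40 genes had a peak and 16 lay above the upper quartile of all genes (4.60 kb). Mn1, a coactivator required for skull bone and palate formation, had 26.0 kb covered and 21.6 ± 4.18 kb over replicates (SD, n = 2). Prrx2, a homeobox gene of craniofacial mesenchyme, had 25.6 kb, with 20.02 and 19.99 kb in the replicates. Alx1, a homeobox gene of the frontonasal region, had 0 kb, with 0.769 ± 1.09 kb over replicates. In the signalling list all 39 genes had a peak and 22 lay above the upper quartile. Ptch1, the Hedgehog receptor, had 19.5 kb (14.2 ± 0.677 kb over replicates), and Axin2, a feedback inhibitor of Wnt signalling, had 18.2 kb (11.9 ± 2.06 kb). Meox2, a homeobox gene of the palate, had 0.458 kb.

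The skeletal lists had higher medians than most random lists without passing the test. Osteoblast genes had a median of 3.76 kb (random 1.84 kb, n = 22 genes, adjusted p = 0.0891), led by Lrp5, a Wnt coreceptor that controls bone mass, with 18.2 kb, and Sp7, the osteoblast factor osterix, with 13.7 kb. Phex, an X-linked regulator of phosphate handling, had 0 kb. The osteoblast list passed with the pooled list, with 20 kb windows and when matched on window GC. Chondrocyte genes had 3.11 kb (random 1.62 kb, n = 20 genes, adjusted p = 0.158), with 14.8 kb at the parathyroid hormone receptor gene Pth1r, 10.5 kb at the cartilage matrix gene Matn3 and 0 kb at Hapln1. This list passed in replicate 1 alone and with 20 kb windows. Housekeeping genes had 4.44 kb (random 2.25 kb, n = 22 genes, adjusted p = 0.0748) and passed with the pooled list, in replicate 2 alone, in the strongest peaks and with 20 kb windows. Rplp0, a ribosomal protein gene, had 17.7 kb and Polr2a, the largest subunit of RNA polymerase II, 9.67 kb, while X-linked Pgk1 had 0.212 kb and 0.645 ± 0.202 kb over replicates (SD, n = 2).

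The lists for other cell types of the face did not pass the test against random lists. Medians were 1.70 kb for tooth (n = 21 genes, adjusted p = 0.799), 2.51 kb for surface ectoderm and oral epithelium (n = 20, 0.606), 2.20 kb for skeletal muscle (n = 19, 0.713), 2.70 kb for endothelium (n = 16, 0.606), 2.66 kb for neurons and Schwann cells (n = 17, 0.606) and 1.89 kb for erythroid and immune cells (n = 18, 0.770). In replicate 2 alone the endothelial median was 1.58 kb and that of surface ectoderm and oral epithelium 1.59 kb. Replicate 2 covered less of the genome, and these medians lay at percentiles 58.8 and 63.1 of random lists for that replicate. Single genes in them were widely covered. Tnnt3, a fast skeletal troponin gene, had 32.9 kb, in a window that overlaps that of Mrpl23, and the intermediate filament gene Des had 13.8 kb, against 0 kb at the myosin gene Myh8. The dental genes Wnt10a and Lef1 had 12.8 kb and 11.6 kb, and the enamel matrix gene Ambn 0 kb. The epithelial regulators Grhl3 and Irf6 had 11.6 kb and 9.02 kb, and the desmosomal gene Dsg3 0 kb. Eng, a coreceptor of endothelial cells, had 11.9 kb and Plvap 7.63 kb, against 0.008 kb at Cdh5, which had 1.06 ± 0.626 kb over replicates (SD, n = 2). The neurotrophin receptor gene Ntrk1 had 12.5 kb and Prph 9.34 kb, against 0 kb at Plp1. The macrophage receptor gene Csf1r had 7.64 kb, in a window that overlaps that of Cdx1, a gene of the gut list. Laptm5 had 7.53 kb, against 0 kb at Alas2, the erythroid enzyme of haem synthesis.

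Lists of other organs did not pass the test either. Liver genes had a median of 0.790 kb (random 2.26 kb, n = 20 genes, adjusted p = 0.158), with 13.1 kb at Apoa2, 4.63 kb at Hnf1a and 0 kb at Afp. The liver list was lower when random lists were matched on window GC (n = 20 genes, adjusted p = 0.0354, against up to 0.401 under the other alternatives). Gut and pancreas genes had 0.884 kb (n = 16 genes, adjusted p = 0.562), although the pancreatic enzyme gene Cpa1 had 27.3 kb. The intestinal factor gene Cdx1 had 16.2 kb, in a window that overlaps that of Csf1r, and the glucagon gene Gcg had 0 kb. Cardiac muscle genes had 2.73 kb (n = 16, 0.562), with 8.65 kb at Myl7, 5.63 kb at Nppb and 0 kb at Ryr2. In replicate 2 alone their median was 1.77 kb, at percentile 74.8 of random lists for that replicate. Forebrain transcription factors had 2.21 kb (n = 16, 0.562), with 25.3 kb at Bcl11b, 6.96 kb at Emx2 and 0 kb at Arx. Germ line genes had 2.28 kb (n = 19, 0.797), with 9.86 kb at Prm1, 7.0 kb at Prm2 and 0 kb at Dazl. The windows of Prm1 and Prm2 overlap.

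The 39 Hox genes of clusters A to D, which pattern the trunk and neck, had a median of 1.57 kb against 4.66 kb in random lists of single genes (n = 39 genes, adjusted p = 0.0113). This call was lost against runs of as many neighbouring genes, a comparison added after seeing the data, where the median lay at percentile 35.6 (n = 39 genes, p = 0.713). The runs were not matched on the number of neighbouring TSSs, and their median was 2.06 kb, so this loss cannot be put down to clustering alone. In replicate 2 alone the Hox median was 1.03 kb, at percentile 0.05 of random lists of single genes for that replicate (n = 39 genes, adjusted p = 0.0051). The call was also lost with 100 kb windows, with the number of peaks and when matched on gene length. The call held when random lists were matched on window GC (percentile 0, n = 39 genes, adjusted p = 0.0017). Matching on gene length or window GC took the place of matching on neighbouring TSSs. HoxD held 9 peaks over 5.71 kb of its 96.8 kb and HoxA 6 peaks over 2.63 kb of 105 kb, while HoxB and HoxC held 1 each. Hoxd8 had 5.17 kb and Hoxd3 4.61 kb in its window, and Hoxb13 0 kb. Of the 34 genes named as the most covered of their lists, 12 had over 1.5 times less covered in a single replicate, 11 of them in replicate 2 and Nppb in replicate 1. The 14 genes given as 0 kb had at most 1.54 kb in a single replicate.

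**Figure D2:**
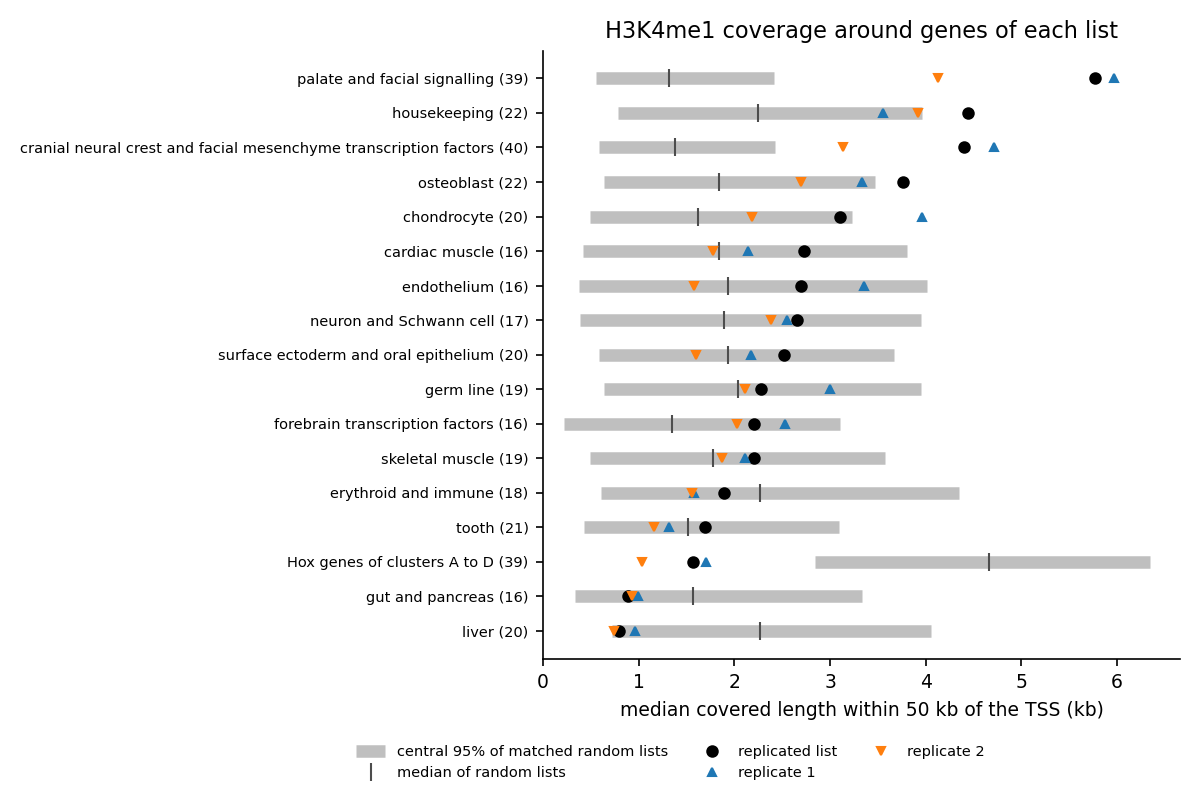
Median covered length within 50 kb of the TSS in kb (horizontal axis) for each gene list with its number of genes (vertical axis): circles are the replicated list, triangles the single replicates, grey bars the central 95% of matched random lists and ticks their median. Bars and ticks are for the replicated list alone, and random lists for the single replicates are not drawn. Palate and facial signalling (5.77 kb) and facial transcription factors (4.40 kb) lie to the right of their bars in all 3 peak lists, and Hox genes (1.57 kb) to the left. The circles of housekeeping genes (4.44 kb) and osteoblast genes (3.76 kb) also lie to the right of their bars, though neither list passed after adjustment.

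In the replicated list, coverage was broadest around Bahcc1, which did not hold in the pooled list or in either replicate. This gene, which encodes a chromatin protein with a BAH domain, had 37.7 kb of its window covered and 29.8 ± 6.08 kb over replicates (SD, n = 2). Rara, the retinoic acid receptor alpha gene, had 37.1 kb (31.2 ± 4.62 kb), and Ski 36.5 kb (31.4 ± 6.33 kb). Mrpl23 had 37.0 kb, Gse1 36.1 kb, Lyl1 35.6 kb, Synpo 35.0 kb (22.4 kb in replicate 2), Ncor2 34.9 kb, Igsf3 34.7 kb and Tcf20 34.5 kb. The median gene had 2.01 kb (quartiles 0.305 and 4.60 kb), and 5112 genes (23.5%) had no replicated peak in the window.

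Peaks were searched for motifs of factors active in the face and elsewhere. Against all flanks, 13 of 21 motifs were denser in peaks and 6 were sparser. Peaks held more GC than flanks (48.8% ± 5.80 against 44.7% ± 6.31, SD over 82470 peaks and 131295 flanks), and pairing on GC, which kept 25442 of the peaks with a mean GC of 46.8%, changed several directions. The palindrome of the nuclear factor I family had the highest ratio, 3.76 (95% interval 2.92 to 5.06), from 148 matches in peaks and 58 in flanks, and 2.05 (1.22 to 4.0) after pairing. With pairing it was 4.0 (2.10 to 10.2) in replicate 1 alone, and replicate 2 alone had too few matches for a ratio. The E-box CAGCTG had 1.60 (1.56 to 1.65) and 1.26 (1.21 to 1.3), and the site of TFAP2, neural crest and ectoderm factors, 1.77 (1.70 to 1.83) and 1.23 (1.18 to 1.29). An E-box and a homeodomain site 4 to 8 bp apart, an arrangement bound by TWIST1 with homeodomain partners in facial mesenchyme, had 1.07 (1.03 to 1.12) and 1.55 (1.43 to 1.71). Without pairing, this ratio did not pass in either single replicate or in the strongest peaks. With pairing it was 1.48 ± 0.00323 over replicates (SD, n = 2). After pairing, TAATTA (1.25) and the E-boxes CAGCTG (1.26) and CATCTG or CAGATG (1.09) were also denser alone, and the E-box CATATG was sparser (0.848). The ratio was not compared with what these parts would give or with other spacings, so the arrangement itself was not tested.

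Sites of several families were denser under both comparisons. MEF2 had ratios of 1.3 (1.20 to 1.43) and 1.94 (1.66 to 2.31) after pairing, FOX 1.11 and 1.39, RUNX 1.22 and 1.38, TEAD 1.27 and 1.33, and the E-box CATCTG or CAGATG 1.13 and 1.09. ETS had 1.78 and 1.48, though after pairing it did not pass in either replicate alone or in unmasked sequence. The homeodomain site TAATTA turned from 0.797 to 1.25 with pairing, the octamer from 0.881 to 1.16 and GATA from 0.815 to 1.04, which was 0.994 and did not pass in unmasked sequence with pairing. The E-box CATATG (0.680 and 0.848) and the SOX site (0.875 and 0.908) were sparser in both, though not in unmasked sequence with pairing. AP-1 (1.03 and 0.969), NRF1 (1.54 and 1.20) and part of the REST site (1.12 and 0.848) passed in the replicated list without pairing but not with it, and AP-1 was sparser in unmasked sequence with pairing (0.925). Without pairing these sites also did not pass in the strongest peaks, nor did AP-1 and part of the REST site in replicate 2 alone. HNF4 passed in neither (0.964 and 0.965), and HNF1 had 1 match in peaks. The core site of CTCF, the insulator protein, was sparser in both, with 0.25 (0.231 to 0.272) and 0.241 (0.20 to 0.285). In unmasked sequence its ratio was 0.862 (0.804 to 0.926), and 0.591 (0.460 to 0.749) with pairing as well.

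**Figure D3:**
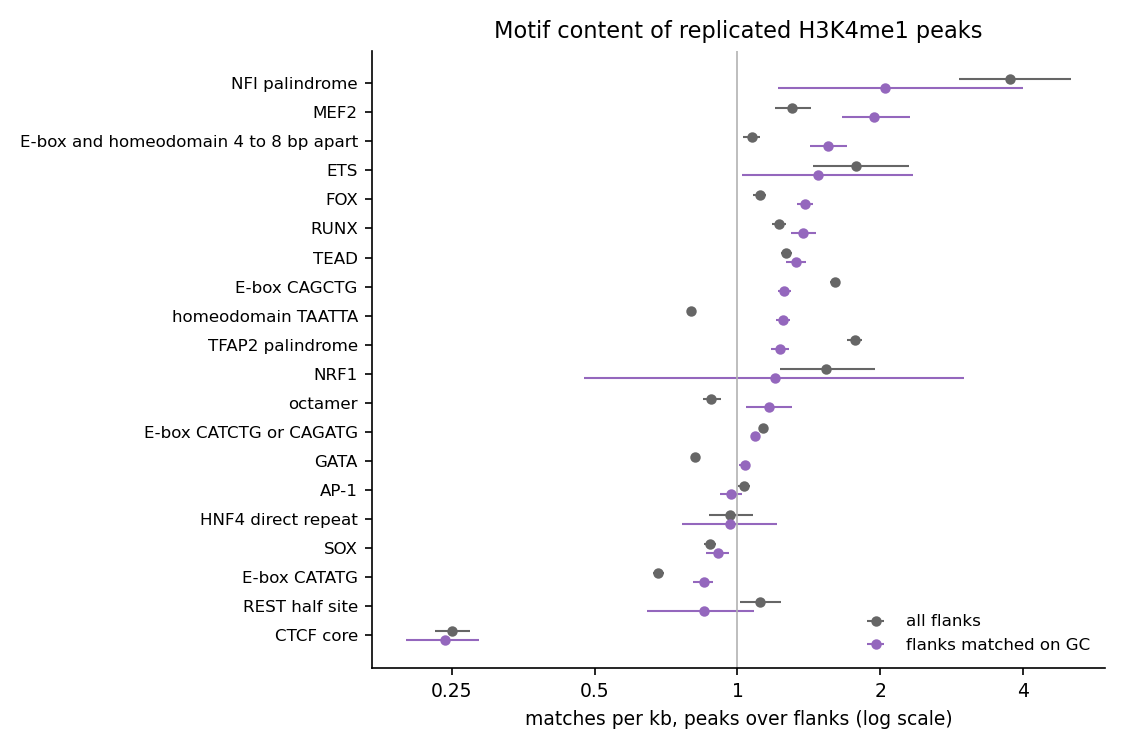
Ratio of motif matches per kb in replicated peaks over flanks (horizontal axis, log scale) for each motif (vertical axis), against all flanks and against flanks paired on GC, with bars for 95% bootstrap intervals over chromosomes. The nuclear factor I site is highest (3.76 and 2.05) and TAATTA changes side, while the CTCF core is lowest with masked repeats included (0.25 and 0.241) and has 0.862 in unmasked sequence, which is not drawn.

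Few peaks lay on the X chromosome. It held 254 replicated peaks covering 0.0683% of its length, against 2.17% ± 0.379 over 19 autosomes (SD, range 1.64% to 3.28%). Its coverage was 0.0314 times the autosomal mean. The ratio was 0.0555 in replicate 2 and 0.0451 in replicate 1, 0.0514 in the pooled list and 0.0152 in the strongest peaks, so its size moved by more than 1.5 times with the list while X stayed below the lowest autosome. Phex, Plp1, Alas2, Arx and Pgk1 are X-linked, but they were named above because they were the least covered of their lists. Their low coverage is therefore no separate evidence on X. In the signalling list, which has 2 X-linked genes, all 39 genes had a peak.

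**Figure D4:**
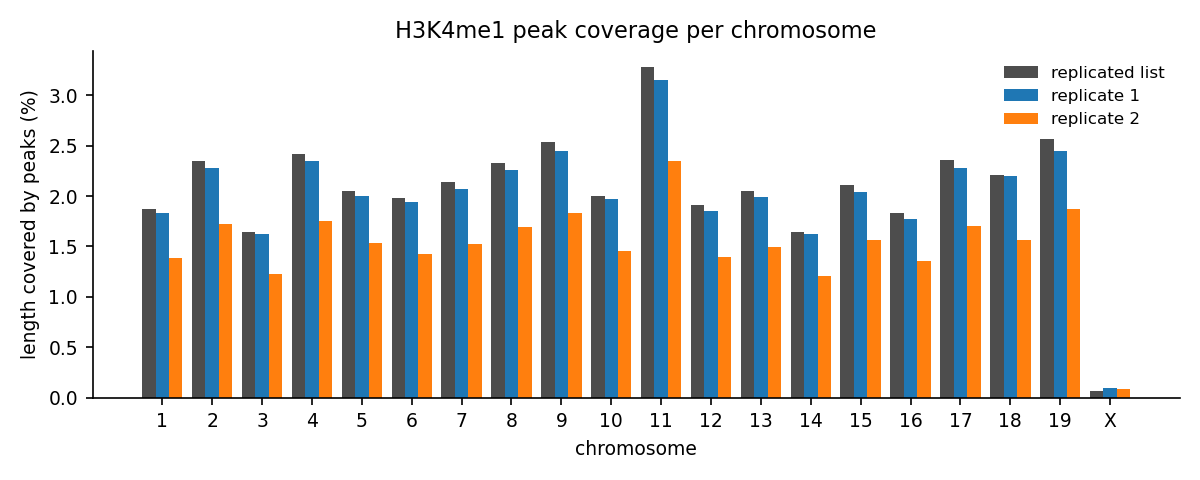
Percentage of each chromosome's length covered by H3K4me1 peaks (vertical axis) by chromosome (horizontal axis), for the replicated list and each replicate as bars. The autosomes lie between 1.64% and 3.28% in the replicated list, and X at 0.0683%.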

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

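The removal of X-linked genes, matching on window GC, runs of neighbouring genes, unmasked sequence and peaks per unmasked Mb were chosen after seeing the data; the other settings were planned. The summary values of the comparisons stayed within their spread or within 1.5 times in 42 cases and moved in 39. These counts mix unlike measures of spread. For overlap and signal correlation the spread treats peaks as independent, so small changes count as moved. For location, TSS coverage and X it is the SD of 2 replicates, and counts of lists and motifs were held to 1.5 times. For single lists and motifs, 309 values kept direction and side of the threshold, 21 fell short of it, 10 newly passed it and 27 changed direction. No paired analysis was possible because the samples form 1 group. Depth is unknown, so its effect on any value could not be measured.

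Overlap shares for replicates 1 and 2 were 47.4% and 59.9% at 1 bp and 16.7% and 30.1% at 80% of the peak length, which follows from the rule itself. They were 25% and 56.0% at a q-value of 0.01 (Jaccard 0.252) and 36.5% and 43.5% with equal numbers of peaks. The signal correlation was 0.240 with a length-weighted mean. The share of replicated peaks in both replicates was 67.6% at 1 bp and 66.7% with 50% of either peak. Promoter and distal shares were 17.1% and 73.8% in the pooled list, 17.4% to 17.8% and 72.2% to 72.9% with 1 replicate left out, 21.9% and 65.8% in the strongest peaks, 16.4% and 74.6% with protein-coding genes alone, and the promoter share was 30.4% at 2 kb. The ratio of the downstream shoulder to the TSS was 3.33 in the pooled list, 3.61 to 3.81 with 1 replicate left out and 4.85 in the strongest peaks. X coverage over autosomes was 0.0514 in the pooled list, 0.0451 to 0.0555 with 1 replicate left out, 0.0152 in the strongest peaks, and 0.0561 as peaks per unmasked Mb. Beyond the overlap rules and promoter width, the cause was not tested.

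Of the gene lists, 4 were higher with the pooled list and 5 with 20 kb windows. The count of lower lists was 0 with 100 kb windows, the number of peaks and matching on gene length, and 2 with matching on window GC. Lists that changed side of the random median did not pass the test before or after. The tooth list went from percentile 60.1 to 33.6 without replicate 2, 35.2 in the strongest peaks, 39.8 with 20 kb windows, 29.9 with 100 kb windows, 33.5 matched on gene length and 40.7 matched on window GC, while without replicate 1 it stayed above the random median at 50.5. Matching on window GC also moved surface ectoderm to 16.5, skeletal muscle to 5.89, endothelium to 41.2, cardiac muscle to 7.67 and forebrain factors to 47.6. Surface ectoderm was at 42.0 in the strongest peaks, germ line at 21.7 with 20 kb windows, neurons at 49.4 and gut and pancreas at 66.1 with 100 kb windows, and erythroid and immune at 58.9 without X-linked genes. The cause was not tested.

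The count of sparser motifs was 3 with pairing on GC and 2 with pairing in unmasked sequence. With pairing, TAATTA turned to 1.25, GATA to 1.04, the octamer to 1.16, AP-1 to 0.969 and part of the REST site to 0.848. With pairing in unmasked sequence, TAATTA was 1.33, the octamer 1.25, AP-1 0.925 and part of the REST site 0.828. AP-1 was 0.973 in unmasked sequence alone, and HNF4 was 1.07 within 500 bp around the summit. The pairing itself removes the GC difference, and the cause of the other changes was not tested. With pairing in unmasked sequence, NRF1 had too few matches for a ratio.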

Other observations

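The gene families below and the comparisons of the Hox list with runs of genes and with the clusters themselves were chosen after the data were seen, as were the GC test of the CTCF site and the spread used to read the signal difference of unshared peaks. Genes grouped by the letters that open their symbols, in families of at least 20, were tested against random lists: of 110 families, 17 had higher and 22 lower coverage, and those named here were picked after their values were seen. No replicated peak lay within 50 kb of the TSS for 1023 of 1134 olfactory receptor genes (Olfr), 317 of 330 vomeronasal receptor genes (Vmn), 59 of 100 cytochrome P450 genes (Cyp), 45 of 57 keratin-associated protein genes (Krtap), 25 of 26 prolactin family genes (Prl), nor for any of the 22 clustered protocadherin beta genes (Pcdhb), 22 major urinary protein genes (Mup) and 34 X-linked Rhox homeobox genes. Tetraspanins (Tspan, median 6.38 kb), semaphorins (Sema, 5.51 kb) and collagens (Col, 3.53 kb) had more coverage than random lists (n = 20, n = 20 and n = 45 genes, adjusted p = 0.00611, 0.0132 and 0.00611). Windows of clustered families overlap, so p-values for them are too small. Few peaks lay anywhere on X, so the absence of peaks at the Rhox genes is no separate evidence on that family.

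Of 17 gene lists, the Hox list alone passed the test of the ratio of coverage between replicates, in windows that overlap and count the same base pairs more than once. Summed over windows, coverage was 72.6 kb in replicate 1 and 43.0 kb in replicate 2, a ratio of 1.69 against 1.3 in random lists (central 95% 1.20 to 1.41, n = 39 genes, adjusted p = 0.0034 over 17 lists). Against runs of neighbouring genes the ratio lay at percentile 98.5 (central 95% 1.07 to 1.64, n = 39 genes, unadjusted p = 0.030). Between the ends of the 4 clusters, where each base pair counts once, coverage was 8.12 kb in replicate 1 and 6.19 kb in replicate 2, a ratio of 1.31 that is close to that of random lists, and HoxB had 0.51 kb against 0.912 kb. The ratio over windows is therefore no measure of the clusters themselves.

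The X chromosome held 4.78 pooled peaks per Mb, 0.0734 times the autosomal density. The tables argue against repeat content and gene density as the cause: X had 0.114 times the lowest autosome's peaks per unmasked Mb and 0.193 times its peaks per gene. Lower copy number alone, in an equal pool of both sexes, would leave 0.782 of autosomal peaks (0.661 to 0.798 over the thresholds tried) if signal scaled with copies, far above the observed ratio. A halved signal, as from 1 active X per cell, would leave 0.146 (0.0912 to 0.159). That range runs from below to above 2 times the observed ratio, so the number of peaks alone cannot decide. Under this scaling the share left falls from 0.159 at a signal of 1.89 to 0.0912 at 2.05, so many peaks would lie between these values. Pooled peaks on X had a median signal of 2.88 (quartiles 2.61 and 3.15), against 2.96 (2.60 and 3.42) on autosomes. X peaks were also narrower, with a median of 274 bp against 333 bp, and had a lower median −log10 p, 4.72 against 5.29. The signals of 1.89 and 2.05 are medians of the autosomal peaks with the highest p-values. Called peaks have passed the authors' threshold, which is unknown, so their signal cannot decide on a plain halving. Each list held peaks on 20 chromosomes, the 19 autosomes and X, and none on Y, although both sexes were pooled. A halved signal, a filter or normalization in the authors' processing and the share of each sex in the pools stay open. No biological explanation was tested against a second group.

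Peaks touching no peak of the other replicate made up 52.6% of replicate 1 and 40.1% of replicate 2. A difference in base composition between the unshared peaks of the 2 replicates is argued against, since their mean GC differed by -0.0004 percentage points. The interval of 2 standard errors, -0.0769 to 0.0761, treats peaks as independent and does not cover variation between libraries. Unshared peaks were weaker than shared peaks, but their median signal lay 0.0359 above the lower quartile of shared peaks in replicate 1 and level with it in replicate 2, so weakness near the threshold may be part of the cause and was not separated. In the strongest 10% by p-value, 85.2% of replicate 1 peaks touched the other replicate and 91.5% of replicate 2 peaks did, up from 30.6% and 39.4% in the weakest 10%, so the bound of 90% was met in 1 replicate and missed in the other. Cell-type makeup stays open: the lowest adjusted p of 10 cell-type lists was 0.900, but a p over the threshold excludes nothing, which makes the bound set beforehand wrong, and depth and the extra input named for replicate 1 were not tested.

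The CTCF core was 0.25 times as dense in peaks as in flanks. Lower GC content of peaks is argued against, since mean GC was 4.05 percentage points higher in peaks than in flanks (interval 3.98 to 4.12), and CpG content was not tested. Most of the deficit lay in masked sequence: 500 of 708 matches in peaks were unmasked, against 705 of 4168 in flanks. Masked sequence made up 12.1% of peaks and 27.4% of flanks, a gap too small to give this difference by itself. Why masked sequence of peaks held fewer matches was not tested. The ratio in unmasked sequence was 0.862 (0.804 to 0.926). It did not reach 1, and with pairing on GC as well it was 0.591 (0.460 to 0.749), so part of the deficit stays open. No biological explanation was tested.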
